A study of Mus musculus with 6 samples.

How the data were processed

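MicroRNA levels were measured by TaqMan RT-PCR in bone marrow-derived macrophages of 3 Dicer WT and 3 Dicer KO mice, all male, 6 to 8 weeks old and lacking Apoe. Per the labels' protocols, total RNA was isolated with the mirVana kit, reverse transcribed with the TaqMan MicroRNA kit and preamplified with the TaqMan PreAmp mix; the instrument, the cycle software and the processing steps were not given in the sources used here. The authors deposited a table of Ct scores with 608 assays (596 miRNA assays, 10 endogenous control assays and 2 assays of a plant miRNA), on a scale that falls by 1 for each doubling of template, with wells without amplification listed at 40. They also deposited a table of relative quantities, each a ratio to the WT samples, and a table of fold changes of KO over WT, both with 596 rows. From their values, the deposited ratio is 2 to the power of minus the Ct after subtraction of the mean Ct of U6, snoRNA135 and snoRNA202 of the same block of rows, divided by the geometric mean of the WT samples, and the deposited fold is the ratio of arithmetic means; wells at Ct 40 entered these as numbers.

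The Ct table was used for all tests. The 2 blocks of rows, each with its own control assays, were called pool A and pool B, and 13 names that occur in both were kept apart. Ct values at or above the ceiling of 35 were set to 35, so a difference from a group at the ceiling is a lower bound. The log2 relative abundance was minus the difference between this Ct and the mean Ct of the 5 endogenous controls of the pool in the same sample. These controls are not made by Dicer, whereas a mean over all miRNAs would remove a common change. An assay was tested if it lay below the ceiling in all 3 samples of at least 1 group, which 282 did; 220 assays were at Ct 40 in all 6 samples. The amount of input is known only through the control Ct values, and the number of samples limits the precision.

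KO and WT were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all tested assays and a threshold of 0.05; adjusted p values of single miRNAs are from this fit. Lists of miRNAs were compared with the other assays by camera with a preset correlation of 0.01, adjusted over the 20 lists with at least 2 tested members of 22 lists; camera was also run with an estimated correlation, under which 0 lists passed. Camera compares a list with the other assays, so its sign can differ from that of the list's median and mean: it was positive for the Dlk1-Dio3 list, which passed, and for the stromal, Sfmbt2 and passenger strand lists, which did not, while their medians and means were negative. The fry test, which asks whether the members of a list move 1 way and not whether they differ from other assays, gave adjusted p values of 0.392 for the stromal and endothelial list, 0.965 for the Dlk1-Dio3 list, 0.691 for the non-miRNA list and at most 0.0186 for the others. Counts per sample and control Ct values were compared by exact permutation tests in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Sample medians were compared by an exact permutation test in R. Figures were drawn with matplotlib 3.10.9.

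The groups share replicate numbers in the labels. Same-number samples deviated together from their group means, with correlations across assays of 0.23, 0.28 and 0.27, beside -0.28 to 0.01 for unlike numbers. The main fit used genotype alone, without a pairing. Outside that fit the numbers were taken to pair the samples, from the data and not from a stated batch. These correlations depend on one another, so they do not establish a pairing. The fit with the replicate number as a block is given beside a result where it changed the call or moved a count by over 1.5 times. With the block 118 assays were lower and 1 was higher, and 92 of the 105 lower assays were lower in both fits, so that 13 were lost and 26 gained. Each named miRNA that fell was lower in KO in all 3 pairs, as were 204 of the 282 tested assays (72.3%). The named falls had already passed the test, so this does not bear on the pairing.

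The design, the lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. Named were the 10 largest falls past the threshold with at least 1 KO sample measured and the 5 largest rises with at least 1 WT sample measured; the 10 most abundant miRNAs of WT; miR-10a, miR-155, miR-146a, miR-21, miR-223, miR-142-3p, miR-342-5p, miR-33, miR-451 and let-7b; each control; up to 5 miRNAs measured in all samples of 1 group and none of the other; and up to 4 members of each list, the 2 with the smallest and the 2 with the largest p. All 89 tested miRNAs given by this rule entered the alternatives, and the text prints part of them. The lists were myeloid and macrophage, inflammation-regulated, lipid handling and oxidative metabolism, lymphocyte, erythroid, stromal and endothelial, and muscle, liver and neural miRNAs, the let-7, miR-15/16, miR-29, miR-30, miR-99/100 and miR-125, miR-181 and miR-200 families, the miR-17-92, miR-23/27/24, Dlk1-Dio3 and Sfmbt2 clusters, mirtrons, a Dicer-independent miRNA, assays taken as non-miRNA transcripts and passenger strands. Membership was set from general knowledge, without a comparison of sequences. Alternatives covered the ceiling, the filter, the reference, the authors' normalized table, the variance model, the block, the threshold and each sample left out. References to the authors' 3 controls and to all 10 controls, a floor set after scaling and the let-7 list without miR-98 were added after the data were seen.

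The fit was tested on simulated data for the comparison of KO with WT. Ct values for the 282 assays were drawn 20 times, with 200 assays changed, from the measured WT means and the mean of the WT and KO variances. Errors were drawn independently for each assay, so shifts shared by the assays of a sample were not simulated. The rates that follow need not hold for the measured data. Of 80 assays lowered by 2 on the log2 scale 42.9% were called, of 80 lowered by 1 8.56%, and of 40 raised by 2 47.5%; 1.30% of the 82 unchanged assays were called. A list of 9 lowered assays had an unadjusted camera p under 0.05 in 19 of 20 draws; the adjustment over lists was not simulated.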

Results

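MicroRNAs were profiled by TaqMan RT-PCR in bone marrow-derived macrophages of male mice aged 6 to 8 weeks, cultured for 7 days in medium with L929-conditioned supernatant, a source of macrophage colony-stimulating factor. All mice lacked Apoe and carried the LysM-Cre driver, which is active in the myeloid lineage. In 3 mice the Dicer gene was wild type (WT), and in 3 mice it was floxed, so that the driver deletes it in myeloid cells (KO). Dicer is the RNase that cuts precursor hairpins into mature miRNAs. The comparison asked which miRNAs of macrophages depend on Dicer and by how much they fall. The panel held no assay of Dicer mRNA, so the genotype in the labels was not checked at the targeted gene.

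The threshold cycle (Ct) was given for 596 miRNA assays, 335 in a first block of rows (pool A) and 261 in a second block (pool B), with 5 endogenous small RNA controls and a plant miRNA in each pool. The plant miRNA, miR159a, was at Ct 40, the value given to wells without amplification, in all 6 samples. The mean Ct of the 5 controls, which stands for the amount of RNA assayed, was 20.2 ± 1.02 in WT and 20.8 ± 1.82 in KO in pool A (SD, n = 3 per group; exact permutation p = 0.8, two-sided), and 19.8 ± 1.12 and 20.2 ± 1.66 in pool B (SD, n = 3; exact permutation p = 0.7). KO replicate 1 had the latest controls. Relative to the mean of its pool, each control (U6, U87, Y1, snoRNA135 and snoRNA202) differed between KO and WT by between -0.18 and 0.28 on the log2 scale. With 3 samples against 3 an exact permutation test cannot give a p under 0.1.

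Fewer miRNAs were detected in KO than in WT macrophages. Below the ceiling of Ct 35, WT samples had 307, 308 and 309 detected miRNA assays (308.0 ± 1.0, SD, n = 3) and KO samples had 219, 277 and 290 (262.0 ± 37.8, SD, n = 3; exact permutation p = 0.1, the smallest possible). In all 3 WT samples 277 assays were detected, in all 3 KO samples 206, and in all 6 samples 201. There were 10 assays detected in all 3 WT samples and in no KO sample, and 0 with the opposite pattern. The let-7 family member miR-98 had Ct values of 23.7, 23.9 and 22.3 in WT and no amplification in KO, at least 2209-fold lower (limma, adjusted p = 0.00222). On the log2 scale this bound was -11.1, and it was -12.1 without KO replicate 1, -10.4 without KO replicate 3 and -9.09 with the floor set after scaling. The other let-7 members were 3.48-fold to 7.49-fold lower, and an assay or plate artefact was not excluded for miR-98. By the same bound miR-1897-3p was at least 282-fold lower (adjusted p = 0.0052), miR-330 (pool A) at least 18.0-fold (adjusted p = 0.0312, 0.0506 with the replicate block) and miR-466b-3-3p at least 14.3-fold (adjusted p = 0.0406, 0.0693 with the replicate block). For miR-1897-3p the bound on the log2 scale was -8.14, and it was -9.10 without KO replicate 1 and -6.22 with the floor set after scaling. The bound for miR-1969 was 10.9-fold, which did not pass the test (adjusted p = 0.11, 0.042 with the replicate block). Without KO replicate 3 miR-466b-3-3p did not pass (adjusted p = 0.0653).

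Most of the miRNAs that WT macrophages expressed were less abundant in KO macrophages. Among 282 assays tested with limma, 105 fell and 1, miR-21*, rose at an adjusted p under 0.05, and 176 did not pass. The median difference was -1.91 on the log2 scale, 3.76-fold lower in KO and 247 of the 282 differences (87.6%) were negative. All KO samples lay below all WT samples in 169 assays (59.9%) and above them in 3. For assays chosen without regard to group, chance gives 10% for both directions together. The filter admitted 277 assays through WT and 206 through KO, 201 of them through both, so this 10% does not hold for the tested set. With assays required in all 6 samples the median difference was -1.82. The assays also share the same 6 samples and are not independent, so the 59.9% does not measure how unlikely the shift is. The median of each sample was -5.41, -5.69 and -5.71 in WT and -8.20, -7.34 and -6.86 in KO, relative to the controls (exact permutation p = 0.1, two-sided). Set against the WT mean, the KO samples were 6.05-fold, 3.34-fold and 2.38-fold lower in replicates 1, 2 and 3. The call of single miRNAs was less firm than the common shift, since 101 of the adjusted p values lay between 0.03 and 0.05: without WT replicate 1, WT replicate 2, WT replicate 3 or KO replicate 2 the number past the threshold was 3, 4, 3 and 4, while without KO replicate 1 or 3 it was 102 and 115. Without any 1 of the former 4 samples, 0 or 1 members of each list passed the threshold, and the counts per list below are from all 6 samples. The global mean, taken per pool over the miRNA assays detected in all 6 samples, removes a common shift. With it as the reference, the median difference was -0.20 and 3 assays passed.

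**Figure D1:**
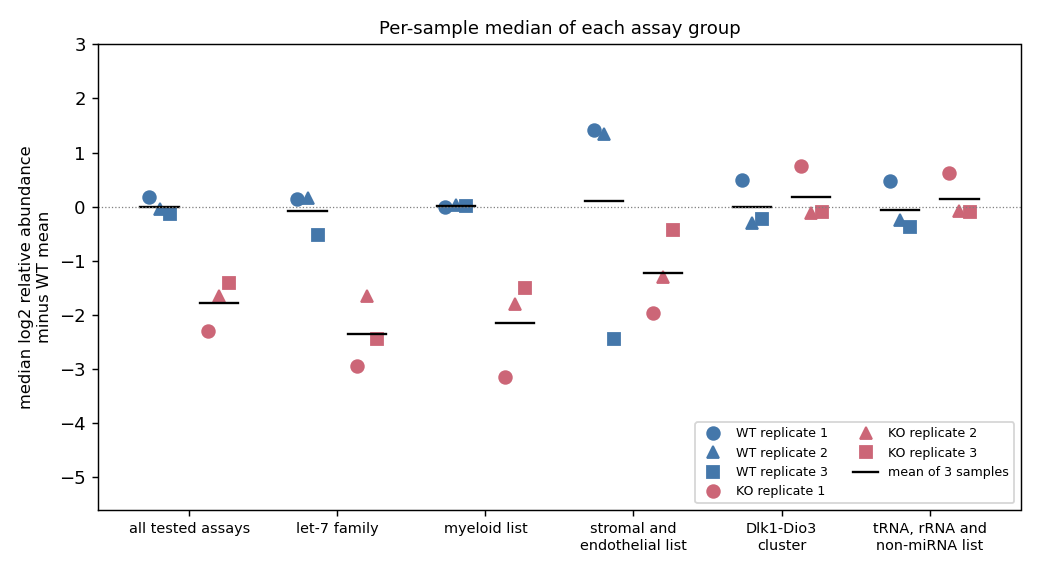
Median log2 relative abundance of 6 groups of assays in each sample, minus the WT mean of each assay. Blue symbols are the 3 WT samples, red symbols the 3 KO samples, marker shapes the replicate numbers and black bars the mean of 3 samples. Over all tested assays the KO samples lie at -2.29, -1.65 and -1.42, whereas for the list of assays taken as tRNA, rRNA and other non-miRNA transcripts they lie at 0.62, -0.08 and -0.10.

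Among abundant miRNAs of myeloid cells miR-223, miR-21 and miR-142-3p fell, while miR-24 (adjusted p = 0.0748, 0.0431 with the replicate block) and miR-146a did not pass the test. miR-223, a regulator of granulocyte and macrophage development, fell 3.75-fold (log2 -1.91 ± 0.58, SE, n = 3 per group; adjusted p = 0.0445), and miR-142-3p, a miRNA of haematopoietic cells, 3.70-fold (-1.89 ± 0.47; adjusted p = 0.0321). miR-21 fell 4.64-fold (-2.21 ± 0.53; adjusted p = 0.0312) and miR-342-5p at least 9.84-fold, with 2 of 3 KO samples below the ceiling (adjusted p = 0.0312). Among the 19 tested members of the list of myeloid and macrophage miRNAs, 9 fell (10 adjusted over the list alone), with a median of -1.99. miR-155, which rises on macrophage activation, was 3.80-fold lower but varied between samples (-1.93 ± 1.01; adjusted p = 0.155). The list as a whole did not pass against the other assays (camera, adjusted p = 0.217). Without KO replicate 1 miR-223, miR-181a and miR-342-3p no longer passed (adjusted p = 0.0663, 0.0506 and 0.0712), without KO replicate 3 miR-223 and miR-181a did not (0.075 and 0.0619), and miR-146a and miR-155 did (0.0458 and 0.0435). Of the 4 lymphocyte miRNAs tested, miR-181a (4.14-fold) and miR-342-3p (8.53-fold; adjusted p = 0.0457, 0.0547 with the replicate block) fell. miR-150 was at -1.19 (adjusted p = 0.326), and 3 fell adjusted over the list alone. With the block 1 lymphocyte miRNA passed, without KO replicate 1 there were 0 and without KO replicate 3 there was 1; the list's median was -2.09 (camera, adjusted p = 0.568).

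Of the 13 inflammation-regulated miRNAs tested, 3 fell (0 adjusted over the list alone) and the median was -2.04 (camera, adjusted p = 0.432); without KO replicate 3 there were 8. miR-147, induced by Toll-like receptor signals, fell at least 8.52-fold with 1 KO sample measured (adjusted p = 0.0443, 0.0759 with the replicate block). miR-146a, a feedback inhibitor of these signals, was at -1.98 ± 0.85 (SE; adjusted p = 0.0985), and miR-212 at -3.01 ± 1.68 (adjusted p = 0.169), or -1.19 without KO replicate 1, where it did not amplify, and -4.59 without KO replicate 3 (adjusted p = 0.0458). Among 14 miRNAs linked to lipid handling and oxidative metabolism, 8 fell (13 adjusted over the list alone), with a median of -2.15 (camera, adjusted p = 0.0627; 0.0279 without KO replicate 1). They included miR-103, which fell 9.35-fold (adjusted p = 0.0311), miR-10a, which fell 4.89-fold (adjusted p = 0.034, 0.0511 with the replicate block), and miR-10b in pool A, which fell at least 15.0-fold (adjusted p = 0.0311). miR-210, a miRNA of the hypoxia response, was at -2.04 (adjusted p = 0.0632, 0.0431 with the replicate block). Without KO replicate 3 miR-147 no longer passed (adjusted p = 0.0618) and miR-210 and miR-146a did (0.0352 and 0.0458). miR-33, which represses cholesterol efflux, was not analysed here.

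The let-7 family had the lowest median of the lists: 8 of 9 tested members fell (9 adjusted over the list alone), the median was -2.35, and the list lay below the other assays (camera, adjusted p = 0.0263; adjusted p = 0.752 with an estimated correlation, 0.0711 with the replicate block). Without miR-98 the list's adjusted p was 0.114. let-7i fell 5.94-fold (-2.57 ± 0.54, SE; adjusted p = 0.0312), let-7b 4.96-fold (adjusted p = 0.0402) and let-7g 4.35-fold (adjusted p = 0.0456), while let-7e was at -1.80 (adjusted p = 0.0504). Without WT replicate 2 or KO replicate 3 the list's adjusted p was 0.0518 and 0.154, and without KO replicate 1 or 3 that of let-7b was 0.0532 and 0.0564.

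The medians of the other families and clusters lay between -2.29 and -1.53, beside -1.91 for all tested assays. None of their lists passed the camera test, which does not show that they moved like the other assays. Of the miR-17-92 and paralogous clusters, which promote proliferation, 3 of 11 tested members fell (3 adjusted over the list alone, 8 with the replicate block; median -1.65, camera adjusted p = 0.432), among them miR-106b (4.50-fold) and miR-18a (4.24-fold), while miR-19b was at -0.85 (adjusted p = 0.183) and miR-92a at -1.03 (adjusted p = 0.194). In the miR-15/16 family 2 of 7 fell (3 adjusted over the list alone, 1 without KO replicate 3; median -1.53, camera adjusted p = 0.439), with miR-497 7.90-fold lower and miR-16 at -1.37 (adjusted p = 0.132). In the miR-29 family 2 of 3 fell (3 adjusted over the list alone, 1 without KO replicate 3; median -2.05, camera adjusted p = 0.432). In the miR-30 family 4 of 5 fell (5 adjusted over the list alone; median -1.96, camera adjusted p = 0.347), among them miR-30d (5.48-fold), while miR-30c was at -1.73 (adjusted p = 0.0564, 0.0464 with the replicate block). In the miR-23/27/24 clusters 3 of 4 fell (4 adjusted over the list alone; median -1.86, camera adjusted p = 0.416), among them miR-27b (4.41-fold), while miR-24 was at -1.84 (adjusted p = 0.0748, 0.0431 with the replicate block). In the miR-99/100 and miR-125 families 5 of 7 fell (5 adjusted over the list alone, 3 without KO replicate 3; median -2.29, camera adjusted p = 0.347), among them miR-100 (4.11-fold), while miR-125a-5p was at -2.92 ± 1.48 (SE; adjusted p = 0.143), or -1.22 without KO replicate 1. Both tested members of the miR-181 family fell (2 adjusted over the list alone; median -1.92, camera adjusted p = 0.439), and there was 1 without KO replicate 1 and 0 without KO replicate 3. Without KO replicate 3 miR-18a no longer passed (adjusted p = 0.0503) and miR-30c did (0.0462).

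Outside these families, the largest falls among assays past the threshold with at least 1 KO sample below the ceiling were those of miR-429 (at least 54.2-fold, 1 KO sample measured), miR-501-3p (at least 44.2-fold if the KO replicate 1 well without amplification is taken as an absence), miR-1306 (at least 30.1-fold, 1 KO sample, adjusted p = 0.0487, 0.056 with the replicate block) and the mirtron miR-1981 (at least 23.9-fold, 2 KO samples). They were followed by miR-466a-3p (at least 22.9-fold), miR-351 (at least 18.7-fold), miR-138 (at least 11.1-fold) and miR-297a* (log2 -3.46 or lower), each with at least 1 KO sample at the ceiling. The bounds of miR-429, miR-1306 and miR-466a-3p, each with 1 KO sample measured, also hold only if the wells without amplification are taken as absences. Without KO replicate 1 the difference of miR-501-3p was -3.64 on the log2 scale, without KO replicate 2 that of miR-1306 was -3.28 (adjusted p = 0.0867), and without KO replicate 3 they were -6.73 for miR-1306 and -7.45 for miR-429. Without KO replicate 1 miR-429, miR-1306, miR-466a-3p and miR-484 no longer passed (adjusted p = 0.0772, 0.13, 0.106 and 0.0532), nor did miR-466a-3p without KO replicate 3 (0.0501). miR-652, measured in all 6 samples, fell 12.3-fold (-3.62 ± 0.84, SE; adjusted p = 0.0312). Of 3 mirtrons and other Microprocessor-independent miRNAs, whose precursors skip Drosha but are cut by Dicer, 2 fell (3 adjusted over the list alone; median -2.24, camera adjusted p = 0.416): miR-1981 and miR-484 (4.74-fold). miR-320 was at -1.67 (adjusted p = 0.0619, 0.0483 with the replicate block), and without KO replicate 1 the list had 1 member that fell. miR-451, whose maturation needs Argonaute2 and not Dicer, had Ct values of 35.5, 34.6 and 40 in WT and 40, 33.0 and 33.5 in KO and was not tested, so the Dicer-independent and the erythroid lists had 0 tested members.

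Some assays were taken as tRNA, rRNA or other non-miRNA transcripts from general knowledge of withdrawn miRNA entries, without a comparison of sequences. Of 9 tested, 0 passed the threshold with limma (0 adjusted over the list alone), their median difference was 0.24, and as a list they lay above the other assays (camera, adjusted p = 7.24e-05; adjusted p = 0.277 with an estimated correlation). Their median turned to -0.03 with U6 alone as reference, to -0.185 without a reference, to -0.02 without WT replicate 3 and to -0.10 without KO replicate 1. miR-720, a tRNA fragment, was at 0.44 ± 0.73 (SE; adjusted p = 0.655), miR-712, from ribosomal RNA, at 0.44 ± 0.60 (adjusted p = 0.598), miR-2146 at 0.09 (adjusted p = 0.895) and miR-2138 at -0.16 (adjusted p = 0.895). Of the 10 most abundant assays in WT, miR-877*, miR-1897-5p, miR-1904, miR-2134 and miR-673 led with differences of 1.01, -0.74, -0.66, -0.22 and 0.86 and adjusted p values from 0.459 to 0.815, and miR-1937c (0.72) and miR-188-5p (0.47) did not pass either. In WT miR-877*, miR-1897-5p and miR-1904 had mean Ct values of 10.5, 10.6 and 10.8, earlier than U6 (14.5 in pool B). Whether these signals come from mature miRNAs was not tested, and an assay artefact was not excluded.

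**Figure D2:**
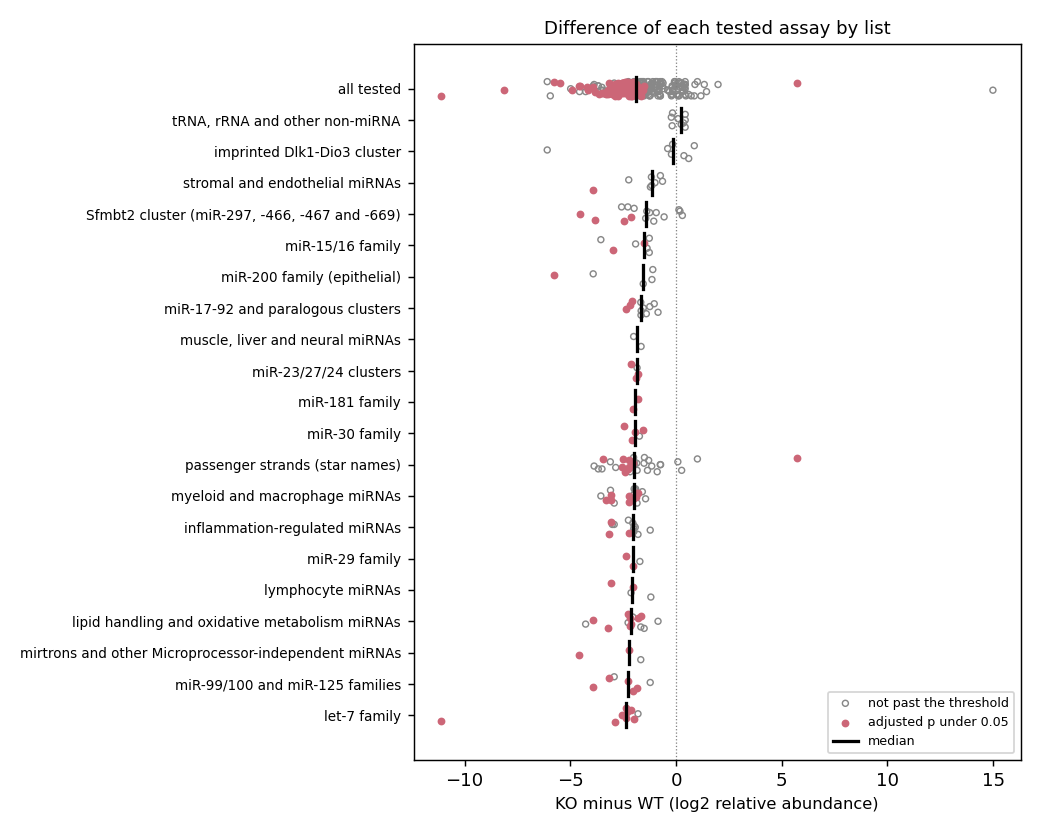
Difference of each tested assay between KO and WT on the log2 scale, by list, in order of the list's median. Filled red points are assays at an adjusted p under 0.05, open grey points did not pass, and black bars are medians. The medians run from -2.35 for the let-7 family to 0.24 for the list of non-miRNA transcripts, and the filled point to the right of 0 is miR-21* at 5.71.

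The only assay that rose, miR-21*, the passenger strand of the miR-21 hairpin, went against its own guide strand. It was 52.4-fold higher in KO (log2 5.71 ± 0.65, SE, n = 3 per group; adjusted p = 0.00537), with Ct values of 31.9, 31.0 and 29.9 in WT and 26.7, 25.7 and 24.5 in KO. An assay or plate artefact was not excluded. Of 31 tested passenger strands, 8 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -1.98 and a mean of -1.63 (camera, adjusted p = 0.744); without KO replicate 3 there were 18 that fell. let-7g* fell at least 5.82-fold with 2 KO samples measured (adjusted p = 0.0312).

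Of 60 assays of the imprinted Dlk1-Dio3 cluster 7 were tested, 0 passed the threshold with limma (0 adjusted over the list alone), the median was -0.16 and the mean -0.72, with members from -6.09 to 0.86, and the list lay above the other assays (camera, adjusted p = 0.00368; adjusted p = 0.277 with an estimated correlation). miR-381, at a mean Ct of 33.7 in WT and so close to the ceiling, was at 0.60 or lower (adjusted p = 0.431). miR-410, also at a mean Ct of 33.7 in WT, was at -0.22 or lower (adjusted p = 0.861). Each had 2 KO samples below the ceiling, so these differences are upper bounds. The highest member, at 0.86, was miR-673, with a mean Ct of 14.5 in WT and also among the most abundant assays. miR-494 in pool A was at -0.16 (adjusted p = 0.813), while miR-495 was at -6.09 ± 3.27 (SE, adjusted p = 0.16) with no amplification in KO replicate 1. Without KO replicate 1 the list had 1 member that fell, miR-495 (-1.86, adjusted p = 0.0414). The median was above 0 without WT replicate 1 (0.44), KO replicate 1 (0.11), KO replicate 2 (0.24) or KO replicate 3 (0.25), with the global mean as reference (1.67) and with assays required in all 6 samples (0.11), and it was 0 with the floor set after scaling. Of the Sfmbt2 cluster 4 of 16 tested assays fell (0 adjusted over the list alone, 2 with the replicate block, 2 without KO replicate 1, 1 without KO replicate 3; median -1.41, camera adjusted p = 0.439), among them miR-467a (pool A), which fell 5.44-fold (adjusted p = 0.0501 without KO replicate 3), while miR-467a in pool B was at 0.19 (adjusted p = 0.844).

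Markers of mesenchymal cells differed between the WT samples. Of 8 stromal and endothelial miRNAs tested, 1 fell (1 adjusted over the list alone; median -1.16, camera adjusted p = 0.432), and that was miR-10b in pool A. The smooth muscle and fibroblast miRNAs miR-143 and miR-145 were at -0.74 ± 1.68 and -0.64 ± 1.83 (SE; adjusted p = 0.752 and 0.804), and the endothelial miR-126-3p at -2.24 (adjusted p = 0.16). In WT replicate 3 miR-143 was 77.8-fold and miR-145 120-fold below the mean of the other WT samples, while miR-10b (pool A), miR-126-3p and miR-126-5p were 1.38-fold, 1.22-fold and 1.85-fold below it, and without WT replicate 3 the list's median was -2.84, with miR-143 at -2.83 and miR-145 at -2.94 (both adjusted p = 0.0733). Against WT replicates 1 and 2 all 8 members were lower in KO, with differences between -1.44 and -4.06. The list's median was -0.54 without WT replicate 1, -0.36 without WT replicate 2 and 0.70 with the global mean as reference. Of 5 epithelial miR-200 family members, 1 fell, miR-429 (3 adjusted over the list alone, 2 with the replicate block, 2 without KO replicate 1 or 3; median -1.55, camera adjusted p = 0.52). miR-141 was at -1.55 (adjusted p = 0.0555, 0.0485 with the replicate block, 0.037 without KO replicate 1), and miR-429 did not pass without KO replicate 1 (0.0772). Of 2 muscle, liver and neural miRNAs tested, 0 passed with limma (1 adjusted over the list alone; median -1.83, camera adjusted p = 0.744), miR-9 was at least 4.01-fold lower (adjusted p = 0.0564, 0.0401 without KO replicate 3, where 1 member passed), and miR-1 and miR-122 stayed at Ct 40 in all 6 samples.

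The authors' deposited table of fold changes gave the same direction as the difference computed here in 94.0% of the 282 tested assays (Pearson r = 0.712 across assays, which are not independent replicates). Of its 596 rows, 563 followed the Ct row of the same name within 0.01 on the log2 scale and 33 held the values of another Ct row. In the authors' deposited table miR-21 had a fold of 0.291 and miR-210 of 0.213, which are the values of the other assay in the Ct table, miR-100 had a fold of 2.39, that of assays without amplification, and miR-1 had 0.252, that of miR-100. Which of the tables carries the right names was not settled, and the values of miR-1, miR-21, miR-210, miR-100, miR-320, miR-466a-3p, miR-466b-3-3p and miR-467a in pool B given above follow the names of the Ct table. Of the 285 deposited folds above 1, 220 came from rows at the value of assays that never amplified, which was 2.39 in pool A and 1.70 in pool B.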

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

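The alternatives with the authors' 3 controls, all 10 controls or a floor set after scaling as well as the let-7 list without miR-98 were chosen after the data were seen. The number of changed miRNAs (106) stayed between 80 and 127 in 18 of 26 alternatives. It was 3 without a filter beyond 1 detected sample, 5 with snoRNA135 alone as reference, 3 with the global mean and 2 with no reference; leaving out 1 sample gave 3 to 115. Many adjusted p values lay just under the threshold, and the cause of each loss was not tested further; with snoRNA135 alone 98 and without WT replicate 2 91 of the 105 lower miRNAs still had an unadjusted p under 0.05, but with the global mean 30 and with no reference 32 had. The median difference stayed between -2.45 and -1.49 except with the global mean (-0.20), which by its construction removes a common shift. Of the 89 miRNAs that the naming rule gave 43 were lower; the number was 26 with a ceiling of Ct 40, 2 without a filter, 4 with snoRNA135 alone, 2 with the global mean, 2 with no reference, 25 with the authors' normalized table and 2 to 38 with 1 sample left out. Of the lists 3 passed the camera test, 5 without a filter, 0 with an estimated correlation and 2 to 4 with 1 sample left out; the let-7 list also lost its call with wells at the ceiling left out or all 6 samples required (both 0.17), with a mean Ct below 30 (0.132), with U6 alone (0.0837) and with the global mean (0.271), and the Dlk1-Dio3 list with no reference (0.0573). The list of non-miRNA transcripts passed under each setting with the preset correlation, with adjusted p values from 1.39e-05 to 0.00555. miR-98 and miR-1897-3p passed in all 22 alternatives that tested them, with adjusted p values up to 0.0232 and 0.042, and miR-21* in 24 of 25, the exception being no reference (adjusted p = 0.177). Reversed with the global mean were miR-15b (0.36), miR-30b (0.34), miR-27a (0.0792), miR-23b (0.00118) and miR-181c (0.10), which were lower past the threshold with the controls as reference. Also reversed were the passenger strands with the global mean, where the list, at a median of -1.33, lay below the other assays (adjusted p = 0.00555), and miR-466a-3p (0.41), miR-466b-3-3p (0.41) and miR-100 (0.64) in the authors' normalized table, where these names hold the values of assays without amplification. A further 66 of 2163 values of named miRNAs changed sign without passing the threshold in either setting. The detected numbers in WT and KO and the share of equal signs with the authors' fold changes kept within 1.5 times; the 10 assays found in all WT and no KO samples became 6 with a ceiling of 32 or 40. Over all tested assays the replicate block ended 13 calls and added 26; among the miRNAs and lists named in the text it changed none other than those given beside their results. A fall near the ceiling is bounded by the cycles left, which limits the precision for scarce miRNAs.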

Other observations

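The tests of input, of the reference, of both strands and their shuffled partners, of early assays in KO replicate 1, of WT replicate 3 and of mesenchymal cells were chosen after the results they measure had been seen; those of the splits and of wells at the ceiling in KO replicate 1 were chosen before. Of 37 hairpins whose tested strands were matched by their assay names, both strands had a negative difference in 35, whether or not it passed the threshold, among them miR-342 (-3.09 for the 3p and -3.30 for the 5p strand). Hairpins whose strands were not matched in this way are not counted. With the partners shuffled between hairpins 10000 times, both were negative in 92.0% of hairpins on average, and a share of 0.0518 gave 35. No shuffle of these values can give more than 35, because so few strands were above 0. That share is set by the number of positive strands, so it cannot decide whether the strands of a hairpin move together. The median gap between strands was 0.62 on the log2 scale, against 0.87 on average in the shuffles, of which a share of 0.0296 had a gap as small. The exceptions were miR-21, with the guide at -2.21 and the passenger strand at 5.71, and miR-463, named after its values were seen, with both strands above 0 (1.99 and 0.09, neither past the threshold). The strands of miR-1897 lay far apart, with -8.14 as a bound for the 3p and -0.74 for the 5p strand, the latter at Ct 9.69 to 11.6 in WT.

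The median difference was -1.99 in the group of assays most abundant in WT, -2.08 in the middle group and -1.51 in the lowest of 3 equal groups of the tested assays. The last value is limited by the ceiling, so that a dependence on abundance was not tested. Pool A had 84 of 179 tested assays lower with a median of -2.03 and pool B 21 of 103 with a median of -1.15; whether the pools differ was not tested. The assay of miR-1937b, named after its values were seen, was at Ct 37.7, 14.3 and 40 in WT and at 14.2, 13.4 and 13.0 in KO, and did not pass the threshold. With the group's other samples below Ct 29, 12 assays did not amplify in KO replicate 1 and 1 (miR-590-5p) in KO replicate 3. WT had 0 such wells. This count leaves out assays that were late or absent in a further sample of the group, such as miR-1937b in WT.

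Most miRNAs were lower in KO, with sample medians at -1.25 or lower against the WT mean relative to the controls. Less RNA or weaker amplification in the KO samples would also delay the controls, which came only 0.573 and 0.429 cycles later in pools A and B where the miRNA median without a reference was -2.45. The list taken from general knowledge as non-miRNA transcripts lay 2.15 log2 units above the median of all tested miRNAs. Its members miR-720, miR-712, miR-2146 and miR-2138 are in pool B, whose median was -1.15, and the list was not compared within each pool. With 1 control alone as reference the weakest median was -1.76. Each control differed between KO and WT by only -0.18 to 0.28 from its pool's mean, so exchanging them could move the median little. A change common to all 5 controls cannot be seen in this way. A loss of Dicer may account for the pattern, but it cannot be told apart from other causes of a general fall, since any of these would also make both strands of most hairpins negative (94.6%) and the strand gap does not separate them either. Among the 10 splits of the 6 samples 1, the real one, gave 106 changed miRNAs, the highest other gave 1 and the highest other of the 4 splits that part all 3 pairs 0, while for the lists past the threshold 1 of 10 splits gave 3 and the highest other 2, and 10 splits are too few for a share under 0.05.

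KO replicate 1 had lower miRNA levels than the other KO samples. Wells at the ceiling or dropped wells did not account for it, because over the 201 assays measured in all 6 samples its median still lay at -0.85 (interval from resampled assays -1.11 to -0.67) against the mean of the other KO samples, beside -0.72 over all tested assays. Low input that loses late assays would leave early ones level, but among assays measured in the 5 other samples the median of the earliest 82 was -0.96 (resampled assays, -1.21 to -0.51), beside -1.29 in the middle and -0.84 in the latest group, the last limited by 35 assays not measured in KO replicate 1. A comparison of late with early assays over those measured in all 6 samples, planned first (-0.0055), was dropped because it leaves out the assays that KO replicate 1 lost. These intervals hold no error between samples, so they speak to which assays carry the shortfall and not to whether another culture would show it, and a more complete deletion of Dicer was not tested.

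The stromal and endothelial miRNAs were low in WT replicate 3. Weaker amplification of this sample as a whole is argued against by its median over all tested miRNAs, -0.17 against the other WT samples. A smaller share of 1 cell population that carries the whole list is argued against as well, since 6 of 8 members were lowest there, and miR-10b in pool A and miR-126-3p, which endothelial cells express, were not. The levels of miR-143, miR-145, miR-199a-3p and miR-214 differed from the other WT samples by -4.93 or lower on the log2 scale, and fewer mesenchymal cells in that culture may be the source, but these miRNAs were picked for the pattern, so this cannot be told apart from other causes. No cell sort is given in the labels.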
